A study of Homo sapiens with 4 samples.

How the data were processed

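RNA was measured in 4 libraries of A549, an established human lung adenocarcinoma cell line with epithelial morphology. Parental A549 cells gave 2 libraries, and the line named TD in the labels gave the other 2. TD cells are A549 cells kept on transforming growth factor beta (TGF-β) at 2 ng/ml, renewed at intervals of 3 days, and both lines grew in medium with 10% serum, per the labels' protocols. Polyadenylated RNA was made into strand-specific libraries with a TruSeq kit after Trizol extraction and DNase treatment. The libraries were loaded at 8 pM and read from both ends for 75 bases on an Illumina NextSeq instrument, per the labels' protocols.

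The deposited values are raw counts per gene, 1 file for each library, with no normalization by the authors visible in the values. FastQC 0.11.8, STAR 2.7.1a (a spliced read aligner) and HTSeq 0.11.2 (which counts reads over annotated genes) are named together with the human build hg19 (GRCh37), per the submitters' processing notes. The annotation release, the strand setting of the counting and any read filter are not given in the sources used here. Because the strand setting is not given, values of antisense and overlapping genes are uncertain. The same holds for members of near-identical families, such as AKR1C1 to AKR1C3, IFNL2 and IFNL3, CGB8, CEACAM5 and CEACAM6, the HLA genes, FTL, FTH1 and the mitochondrially encoded genes with nuclear copies. Each file ends with totals of reads that HTSeq gave to no gene, and these were kept out of library sizes and tests. Reads outside annotated genes made up 6.86% and 6.12% of all counted reads in A549 replicates 1 and 2, and 7.79% and 6.51% in TD replicates 1 and 2. Reads in more than 1 gene made up 2.34% to 2.56%, and reads with more than 1 alignment made up 8.08% to 9.22%.

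The files list 57820 Ensembl gene identifiers, of which 52338 were paired with a symbol and a gene type from GENCODE 29. That annotation is on GRCh38, another build than that of the files, so it served only for names, gene types, base composition, chromosome and gene order, and no coordinates are given. Among the tested genes, 447 had no symbol. No pair of libraries held identical values. Gene counts per library came to 26729278 and 29381872 for A549 and to 28237849 and 44133836 for TD. At these totals, 3 counts in a library, taken as the limit that a count of 0 allows, correspond to 0.068 to 0.112 CPM (counts scaled to a common library size). Intervals and limits of this kind cover counting error only.

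The comparison of TD with A549 used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, the default expression filter (a minimum count of 10) and Benjamini-Hochberg adjustment. Genes were called at an adjusted p below 0.05. Levels are CPM on the TMM scale, given as mean ± SD of 2 libraries, and changes are log2 ratios of TD over A549 with a standard error (SE) taken from the fitted change and its F statistic. A fold against a group without any count is a lower bound that sets 3 counts over the group in place of 0. With 1 to 3 counts in a group, the ratio is given with its 95% exact counting interval. The labels do not say that the libraries of a group came from separate cultures, so all p-values measure only the spread between these libraries, which may be technical.

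The design, the 25 gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. Named genes were the 10 largest rises and 10 largest falls among called genes with at least a 2-fold change, a mean of at least 10 CPM in the higher group, a symbol and no overlap between the groups. Further named genes were the 2 called members with the largest change in each direction of each list, and, whatever their result, CDH1, CDH2, VIM, FN1, SNAI1, SNAI2 and ZEB1. Some genes that the rule names are not reported here. Members named outside this rule were chosen after their values were seen. The 22 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01. Their p-values were adjusted over those lists. Camera was repeated with the correlation estimated from these libraries, in which case it also takes its p from the few residual degrees of freedom. The test fry asked whether the members of a list moved, on balance, in 1 direction.

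Alternatives covered scaling by DESeq2 size factors, upper quartiles or library totals, the tests of DESeq2 1.42.0 and limma-voom, no filter, and a filter of 5 CPM in 2 libraries. They also covered robust dispersion, thinning of all libraries to the smallest total, the replicate number as a block, leaving out each library, leaving out the 20 most abundant genes, protein-coding genes only, and edgeR's test against a 1.5-fold change. Leaving out all pseudogenes was added after seeing the data. With 1 library left out, the remaining library of that group is assumed to vary like the pair of the other group.

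The steps were tested on simulated counts drawn from the A549 means and the library sizes of all 4 libraries, with 200 changed genes among 16848 tested. edgeR recovered 59% of the 2-fold changes and 88% of the 4-fold changes, and it called 12 unchanged genes. The spread was the one fitted to all 4 libraries, and far fewer genes were changed than the 7642 called in the data. These shares are therefore not the sensitivity of the comparison itself. The planted gene list was found, and 0 of 20 unchanged lists were called. Each gene was drawn independently, so these lists had no correlation between members. They do not show how often camera calls an unchanged list whose members are correlated. Tests on gene order used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.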

Results

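The data comprised 4 libraries of bulk RNA, 2 from parental A549 lung adenocarcinoma cells and 2 from TD cells, which are A549 cells maintained on TGF-β, a cytokine that drives epithelial cells toward a mesenchymal state. Libraries held 26729278 and 29381872 gene counts for A549 and 28237849 and 44133836 for TD. The only comparison the labels imply is TD against A549, which asks how the RNA of the TGF-β-maintained, mesenchymal-like cells differs from that of the parental cells.

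TD cells differed from parental cells in a large part of the expressed genome. The gene with the highest TD level among the largest rises was ADAM19, a membrane metalloprotease, which went from 0.630 ± 0.176 to 623 ± 30.8 CPM. SPOCK1, a secreted proteoglycan, went from 0.0865 ± 0.0207 to 192 ± 2.61 CPM. GDF6, a ligand of the bone morphogenetic protein family, had 0 counts in A549 and 24.1 ± 3.79 CPM in TD, at least 470.1-fold higher. LINC01583 and MYCT1 also had 0 counts in A549 and were at least 315-fold and 219.5-fold higher in TD. ACKR3, an atypical chemokine receptor, was 2169-fold higher by counts (95% interval 600.1 to 17912). FLRT2 was 1410-fold higher (482 to 6841), TMEM132E 1272-fold (228 to 50260) and CGB8 1743-fold (312 to 68872), the last from a family of near-identical gonadotropin genes. Among the falls, NTS, which encodes the peptide neurotensin, went from 1747 ± 38.9 to 0.172 ± 0.00012 CPM, with 100500 counts in A549 and 12 in TD. VIL1, the microvillus protein villin, went from 162 ± 1.57 to 0.0836 ± 0.0208 CPM. DEFB1, an antimicrobial defensin, was 6695-fold lower by counts (1201 to 264490). SCEL, XAF1, CEACAM6, CST1, TRIM31, MUC5AC and KRT4 had 0 counts in TD and were at least 248-fold to 1124-fold lower. All of these genes had an adjusted p of at most 0.000641 by edgeR's quasi-likelihood test. In all, 7642 of 17785 tested genes (43.0%) were called, 3833 higher and 3809 lower in TD, with 1688 at least 2-fold higher and 2184 at least 2-fold lower. With an A549 library left out, the spread was estimated from the TD pair alone. The coefficient of variation was then 34.1% without A549 replicate 1 and 34.0% without A549 replicate 2, against 20.1% with all libraries. A call lost in this way, here and below, can reflect that spread rather than a changed fold. With pseudogenes left out and all libraries kept, the coefficient was 7.90%, and no named gene lost its call. No library was left out in that setting, so how far pseudogenes account for the lost calls was not tested. The counts of called genes depended on which libraries entered. Without A549 replicate 1 they fell to 2114 higher and 2236 lower, with 1444 at least 2-fold lower, and without A549 replicate 2 to 2241 and 2251. Without TD replicate 1, 6140 genes were lower and 4096 at least 2-fold lower, of which 1787 and 1742 were pseudogenes, against 175 of 3809 and 158 of 2184 with all libraries.

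Epithelial genes fell and mesenchymal genes rose in TD. CDH1, which encodes the epithelial adhesion molecule E-cadherin, dropped from 189.9 ± 1.86 to 2.95 ± 0.134 CPM, a log2 change of -6.00 (SE 0.09, adjusted p = 3.08e-05 by edgeR). CDH2, N-cadherin, rose from 0.485 ± 0.0765 to 187 ± 13.4 CPM (8.58, SE 0.15, adjusted p = 3.08e-05). VIM, the intermediate filament vimentin, rose from 368 ± 3.67 to 1657 ± 260.3 CPM (2.17, SE 0.14, adjusted p = 0.000419). FN1, fibronectin, rose from 64.6 ± 1.09 to 611 ± 54.4 CPM (3.24, SE 0.10, adjusted p = 6.32e-05). Of 32 tested epithelial genes, 26 fell and 2 rose, with the same counts when adjusted over the list alone (camera adjusted p = 6.86e-22, adjusted p = 0.078 with an estimated correlation). EPCAM, an epithelial surface adhesion molecule, fell from 151 ± 3.83 to 0.15 ± 0.066 CPM. MAL2, a protein of apical transport, was 883-fold lower by counts (95% interval 158 to 34940). The 2 that rose were TJP1, the junction scaffold ZO-1, from 132 ± 7.55 to 220.5 ± 1.81 CPM, and the protease gene PRSS8, from 0.156 to 0.61 CPM. PRSS8 lost its call without A549 replicate 1 (adjusted p = 0.18) and without A549 replicate 2 (0.152). Its adjusted p was 0.0987 by DESeq2. Of 24 mesenchymal genes, 17 rose and 3 fell, and 19 and 3 did when adjusted over the list alone (camera adjusted p = 3.00e-25, adjusted p = 0.147 with an estimated correlation). SPARC, a matrix glycoprotein, was 255-fold higher by counts (70.3 to 2110.3). The 3 that fell were S100A4, a calcium-binding protein, from 416 ± 73.5 to 62.9 ± 1.45 CPM, LUM, the proteoglycan lumican, from 1.39 to 0.16 CPM, and ACTA2, smooth muscle actin, from 10.6 to 4.49 CPM.

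Transcription factors known to repress epithelial genes also rose. SNAI2 had 0 counts in A549 and 14.9 ± 1.03 CPM in TD, at least 287-fold higher (adjusted p = 0.000162). SNAI1 rose from 10.2 ± 0.0306 to 35.4 ± 5.47 CPM (1.79, SE 0.13, adjusted p = 0.000648), and ZEB1 rose from 14.6 ± 0.00585 to 54.0 ± 2.98 CPM (1.89, SE 0.08, adjusted p = 0.000132). ZEB2 rose from 0.104 ± 0.00471 to 12.0 ± 1.00 CPM. Of the 12 tested factors of this list, 8 rose and 1 fell, and 9 and 1 did when adjusted over the list alone (camera adjusted p = 8.60e-07, adjusted p = 0.402 with an estimated correlation). The member that fell was the forkhead gene FOXQ1, from 12.4 ± 0.288 to 1.97 ± 0.204 CPM. TWIST1 had means of 0.4 CPM in A549 and 0.866 CPM in TD and was not called (adjusted p = 0.0709).

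**Figure D1:**
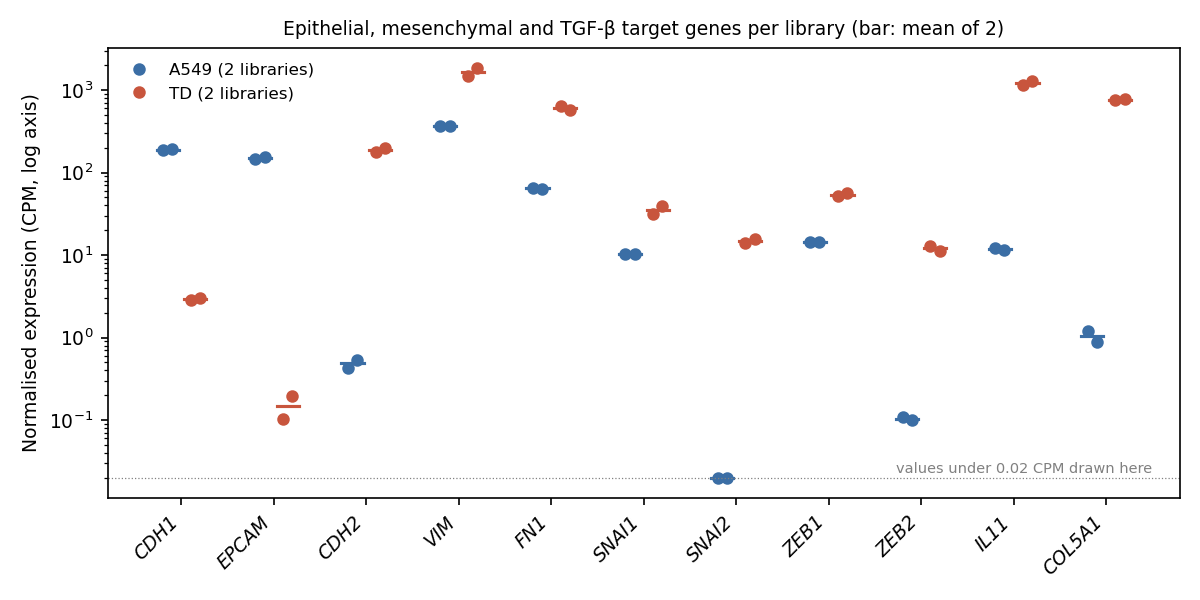
Expression in CPM (log axis) of epithelial, mesenchymal, transcription factor and TGF-β target genes in the 2 A549 and 2 TD libraries, with each point a library and each bar the mean of 2. CDH1 and EPCAM lie lower in both TD libraries and the other genes drawn lie higher, with SNAI2 at 0 counts in both A549 libraries.

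Known targets of TGF-β were mostly higher in TD. IL11, a cytokine of the interleukin 6 family, rose from 11.8 ± 0.482 to 1226 ± 81.5 CPM (log2 change 6.70, SE 0.12, adjusted p = 3.08e-05). Of 29 tested targets, 20 rose and 5 fell, with the same counts when adjusted over the list alone (camera adjusted p = 3.00e-25, adjusted p = 0.199 with an estimated correlation). The members that fell included ID2, from 102 ± 4.46 to 4.79 ± 1.02 CPM, and ID1, from 155 ± 19.96 to 31.7 ± 3.85 CPM, both inhibitors of basic helix-loop-helix factors that bone morphogenetic proteins are known to induce. The other members that fell were IGFBP3, SMAD6 and TGIF1. Among 29 tested components of the pathway, 13 rose and 9 fell, and 15 and 10 did when adjusted over the list alone, and the list was not called by camera (adjusted p = 0.0757). BMP2 rose from 1.63 ± 0.320 to 28.5 ± 3.92 CPM, and NOG, an antagonist of bone morphogenetic proteins, had 0 counts in A549 and was at least 27.8-fold higher. BMP4 fell from 27.0 ± 2.62 to 1.71 ± 0.225 CPM and SMAD9 from 1.73 ± 0.152 to 0.148 ± 0.0349 CPM. Without A549 replicate 2, the number of components that fell was 5. Camera called this list without TD replicate 1 (adjusted p = 0.0197).

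Genes of the extracellular matrix and of its receptors and proteases changed together with these. COL5A1, a fibrillar collagen chain, rose from 1.03 ± 0.219 to 763 ± 17.5 CPM and COL1A1 from 3.79 ± 0.0750 to 278 ± 25.1 CPM. Of 29 collagens and crosslinking enzymes, 19 rose and 4 fell, and 21 and 4 did when adjusted over the list alone (camera adjusted p = 7.16e-17, adjusted p = 0.078 with an estimated correlation). COL4A3 and COL4A4, basement membrane collagen chains, fell from 25.9 ± 1.49 to 3.46 ± 0.371 CPM and from 54.7 ± 1.84 to 10.1 ± 0.588 CPM. The number that fell was 2 without A549 replicate 2 and 7 with pseudogenes left out. Of 22 integrins and laminins, 14 rose and 8 fell, with the same counts when adjusted over the list alone (camera adjusted p = 8.60e-07, adjusted p = 0.17 with an estimated correlation). ITGB3 rose from 0.21 ± 0.0587 to 29.9 ± 3.84 CPM. LAMA3, a laminin chain of epithelial basement membranes, fell from 59.5 ± 4.53 to 4.15 ± 0.0145 CPM. ITGB8 fell from 1.22 to 0.0812 CPM but was not called without A549 replicate 1 (adjusted p = 0.107) or replicate 2 (0.1), and 5 members of this list fell without either of these libraries. Of 18 proteases and inhibitors, 12 rose and 5 fell, and 12 and 6 did when adjusted over the list alone (camera adjusted p = 9.66e-15, adjusted p = 0.192 with an estimated correlation). Besides SPOCK1 and ADAM19, SERPINE2 rose from 4.30 to 296 CPM and TIMP2 from 36.1 to 830.0 CPM. ADAMTS1 fell from 1.76 ± 0.0547 to 0.202 ± 0.0071 CPM and MMP7, the protease matrilysin, from 7.46 ± 0.115 to 1.36 ± 0.166 CPM.

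Interferon-stimulated genes were lower in TD without exception in the list. All 30 tested members fell by at least 2-fold, with the same count when adjusted over the list alone (camera adjusted p = 1.52e-83, adjusted p = 0.078 with an estimated correlation). XAF1 and MX2 had 0 counts in TD and were at least 578-fold and 125-fold lower. IFIT1, an antiviral RNA-binding protein, fell from 714 ± 88.4 to 5.60 CPM and ISG15 from 356 to 9.06 CPM. Of 17 tested genes of antigen presentation and checkpoint ligands, 10 fell and 3 rose, and 11 and 4 did when adjusted over the list alone, and the list was not called by camera (adjusted p = 0.109). PSMB8, an immunoproteasome subunit, fell from 16.9 ± 0.220 to 1.39 ± 0.126 CPM and LGALS9 from 5.75 ± 0.702 to 0.288 ± 0.129 CPM. The 3 that rose were NT5E, the adenosine-producing enzyme CD73, from 22.7 ± 2.27 to 265 ± 15.6 CPM, CD274, the checkpoint ligand PD-L1, from 3.79 ± 0.640 to 11.7 ± 0.840 CPM, and CD47. Camera called this list without A549 replicate 2 (adjusted p = 0.0468) and without TD replicate 2 (0.0133), and 5 members rose without TD replicate 1, by DESeq2's test, with no filter for low counts, with protein-coding genes alone and with pseudogenes left out. Cytokines and chemokines went both ways, with 6 of 17 higher and 8 lower, the same counts as when adjusted over the list alone (camera adjusted p = 0.895). IL6 rose from 0.244 ± 0.011 to 18.8 ± 1.36 CPM and IL1A from 0.262 ± 0.0364 to 9.20 ± 0.104 CPM. TNFSF10, the death ligand TRAIL, was 194-fold lower by counts (95% interval 34.3 to 7705), and CX3CL1 was 89.7-fold lower (24.4 to 747).

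Metabolic lists were mostly lower in TD. NRF2 is a transcription factor of the oxidant response that is constitutively active in A549. Of its 30 tested targets, 25 fell and 0 rose, and 28 and 0 did when adjusted over the list alone (camera adjusted p = 6.86e-22, adjusted p = 0.204 with an estimated correlation). The fitted change was below 0 for each of the 30. GPX2, a glutathione peroxidase, fell from 729 ± 20.8 to 1.46 ± 0.121 CPM and ALDH3A1, an aldehyde dehydrogenase, from 969 ± 19.9 to 89.4 ± 21.1 CPM. NQO1 fell from 2015 to 1113 CPM, while SLC7A11, the cystine transporter, had means of 369 and 324 CPM and was not called (adjusted p = 0.131). Of 29 genes of glycolysis and the hypoxia response, 19 fell and 2 rose, and 21 and 3 did when adjusted over the list alone (camera adjusted p = 5.48e-05, adjusted p = 0.534 with an estimated correlation). ADM and CA9 fell from 55.5 ± 0.782 to 1.90 ± 0.402 CPM and from 9.93 ± 0.0791 to 0.426 ± 0.163 CPM. VEGFA, the angiogenic growth factor, rose from 47.8 ± 5.08 to 369 ± 13.0 CPM, and PFKFB4 rose from 6.29 ± 0.257 to 20.2 ± 3.15 CPM. The number of members that fell was 12 without either A549 library. Of 24 genes of cholesterol synthesis and uptake, 12 fell and 2 rose, and 13 and 3 did when adjusted over the list alone (camera adjusted p = 0.00233, adjusted p = 0.557 with an estimated correlation). TM7SF2, a sterol reductase, fell from 7.64 ± 0.688 to 1.03 ± 0.243 CPM. INSIG1 rose from 35.1 to 126 CPM. The number of members that rose was 1 without either A549 library. Of 17 genes of ferroptosis and glutathione use, 7 fell and 5 rose, the same counts as when adjusted over the list alone (camera adjusted p = 0.109). PTGS2, the prostaglandin synthase COX-2, fell from 83.5 ± 5.53 to 5.23 ± 0.0416 CPM and CHAC1 from 5.50 to 1.12 CPM, while ACSL4, which activates polyunsaturated fatty acids, rose from 42.4 ± 3.70 to 218 ± 18.6 CPM. LPCAT3 rose from 21.3 to 34.2 CPM but was not called without A549 replicate 1 (adjusted p = 0.104) or 2 (0.0927), which each left 2 risers in this list.

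The lung epithelial lineage genes that could be tested were mostly lower. The surfactant genes SFTPA1, SFTPA2, SFTPB and SFTPC and the gene NKX2-1 were not tested. They had at most 6 counts in any library, parental or TD, so a loss of their RNA in TD cannot be read from these data. MUC5B, a secreted airway mucin, fell from 612 ± 117 to 0.905 ± 0.354 CPM, and MUC5AC, its paralog, had 722 counts in A549 and 0 in TD. Of 13 tested lineage genes, 10 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 8.60e-07, adjusted p = 0.147 with an estimated correlation). The member that rose was ABCA3, a lipid transporter of alveolar cells, from 28.1 ± 0.356 to 47.4 ± 8.20 CPM, a call lost without A549 replicate 1 (adjusted p = 0.0732) and replicate 2 (0.0725), which each left 0 risers, against 2 without TD replicate 1. Of 26 YAP targets, 13 rose and 8 fell, and 14 and 8 did when adjusted over the list alone (camera adjusted p = 0.000839, adjusted p = 0.417 with an estimated correlation). CCN2, a matricellular growth factor that TGF-β also induces, rose from 4.10 ± 0.209 to 201 ± 13.3 CPM and RBMS3 from 0.261 to 6.90 CPM. MYOF, a membrane repair protein, fell from 475 ± 14.5 to 106 ± 2.68 CPM and AMOTL1 from 85.6 to 39.7 CPM. Camera did not call the YAP list without A549 replicate 2 (adjusted p = 0.066), with the stricter filter (0.13) or with limma-voom (0.0503). Of 21 receptor tyrosine kinases, 7 rose and 8 fell, and 8 and 10 did when adjusted over the list alone (camera adjusted p = 0.97). EPHB2 rose from 18.6 ± 0.297 to 340.5 ± 28.0 CPM and RET from 0.579 to 13.2 CPM. ERBB3 fell from 55.8 ± 0.699 to 0.802 ± 0.230 CPM and FGFR3 from 37.2 ± 5.78 to 2.60 ± 0.116 CPM. AXL, often named with the mesenchymal state, fell from 79.5 to 43.1 CPM (log2 change -0.88, SE 0.11, adjusted p = 0.00371). Of 15 drug transporters and stem-like markers, 5 rose and 5 fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.482). CD44 rose from 213 ± 2.67 to 618 ± 39.5 CPM, and LGR5 rose from 0.0865 to 0.996 CPM, a call lost without A549 replicate 1 (adjusted p = 0.0556), which left 3 risers. ABCB1, the efflux pump P-glycoprotein, fell from 24.5 ± 1.90 to 0.226 ± 0.0277 CPM. LGR6 was 57.0-fold lower by counts (95% interval 9.74 to 2297), with no call without A549 replicate 1 (adjusted p = 0.0686) or 2 (0.0727).

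Proliferation genes went both ways. Of 32 tested, 10 rose and 12 fell, and 11 and 13 did when adjusted over the list alone, none by as much as 2-fold (camera adjusted p = 0.97). BIRC5 and CENPF, both of mitosis, rose from 115 ± 2.89 to 208 ± 25.4 CPM and from 203 ± 18.6 to 349.7 ± 17.9 CPM. CDK1 fell from 192 ± 13.0 to 115 ± 2.82 CPM and E2F1, a driver of S phase, from 51.2 ± 2.28 to 32.7 ± 3.20 CPM. The counts were 7 lower without A549 replicate 1, and 6 higher and 6 lower without A549 replicate 2. For the proliferation, receptor tyrosine kinase and mitochondrial lists, and for the drug transporter list, the direction of camera, the mean and the median did not all have the same sign.

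**Figure D2:**
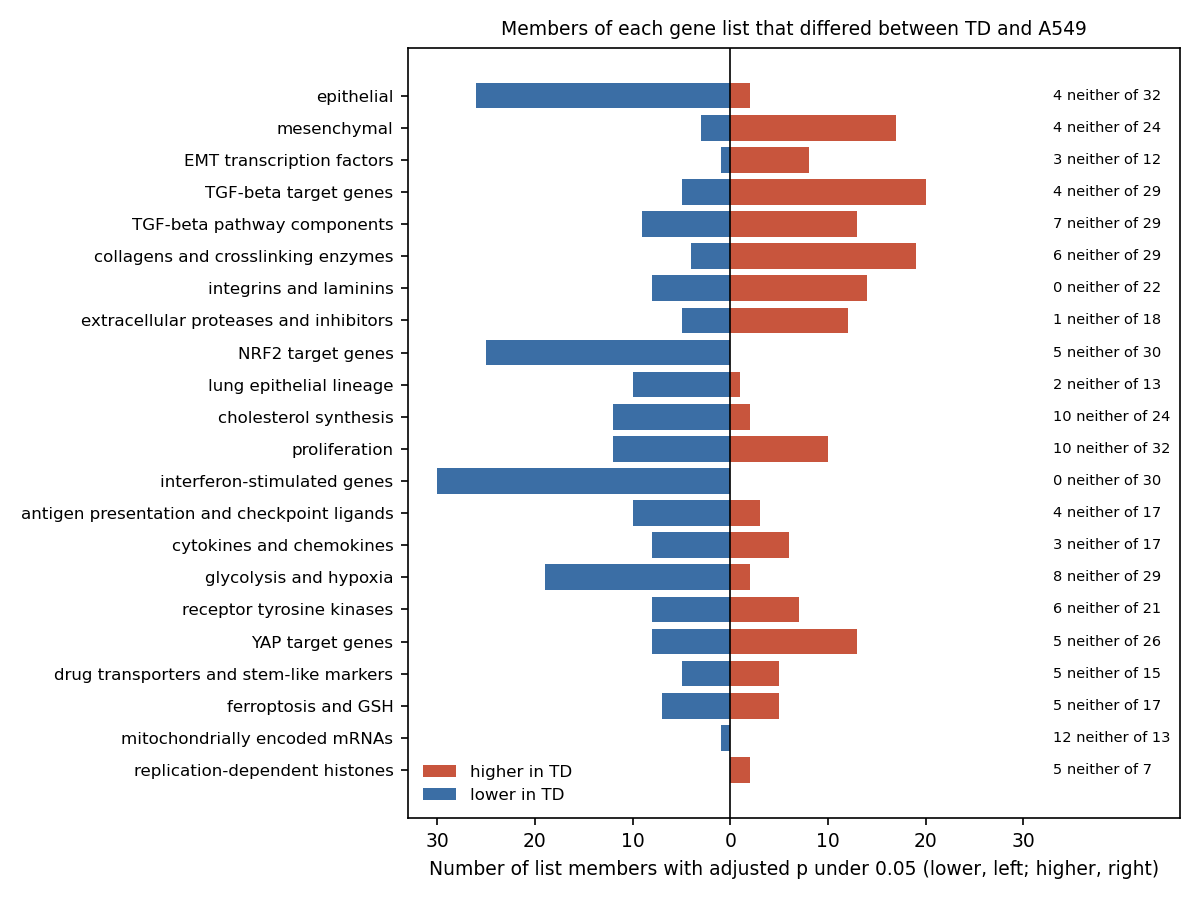
Number of members of each gene list with an adjusted p under 0.05 that were lower in TD (bars to the left) or higher in TD (bars to the right), with the number of tested members that were neither written at the right. The 30 interferon-stimulated genes all lie to the left, as do 25 of 30 NRF2 targets and 26 of 32 epithelial genes.

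Most markers of blood cells, fibroblasts and endothelium did not pass the expression filter. Of 12 blood cell markers, 3 were tested, and CD14 fell from 0.801 to 0.258 CPM, with no call when adjusted over the list alone, without A549 replicate 1 (adjusted p = 0.248) or 2 (0.227), or by DESeq2 (0.121). Of 11 fibroblast markers, 3 were tested: COL3A1 rose from 0.0707 to 0.586 CPM, LUM fell, and FBLN1 fell from 38.5 to 27.7 CPM, with the same counts when adjusted over the list alone. COL3A1 lost its call without A549 replicate 1 (adjusted p = 0.0802) or 2 (0.137), and so did FBLN1 (0.107 and 0.063). Of 10 endothelial markers found in the files, 3 were tested, and ESAM rose from 2.10 ± 0.176 to 28.3 ± 1.501 CPM. ERG was 13.5-fold higher by counts (95% interval 4.35 to 67.6), a call lost without A549 replicate 1 (adjusted p = 0.0565) or 2 (0.073). These counts were the same when adjusted over the list alone. With no filter for low counts, 5 endothelial markers were higher, as KDR, TEK and ROBO4, each with 0 counts in A549 and 22 in TD, were then called too. CDH5 had 3 counts in A549 and 2 in TD, and VWF had 1 and 0. Of 13 mitochondrially encoded mRNAs, MT-ND3 alone was called, falling from 952 ± 125 to 590.5 ± 127 CPM, and it was not called when adjusted over the list alone (camera adjusted p = 0.97). MT-ND3 lost its call without A549 replicate 1 (adjusted p = 0.0745) or 2 (0.146), while 6 of the 13 were higher without TD replicate 1, and 1 higher and 5 lower without TD replicate 2. Mitochondrial genes held 9.37% and 10.6% of gene counts in A549 replicates 1 and 2, and 11.1% and 12.9% in TD replicates 1 and 2. Of 7 tested replication-dependent histones, H2BC11 and H2AC6 rose, from 3.51 to 8.59 CPM and from 13.8 to 29.8 CPM, with the same count when adjusted over the list alone (camera adjusted p = 0.505). Without TD replicate 2, 1 histone gene was lower.

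Replicates were closer to each other than to the other group. Across genes of log2 CPM, which are not independent replicates, r was 0.994 between the A549 libraries, 0.967 between the TD libraries and 0.865 to 0.88 between groups. Both pairs differed by more than sampling noise, with a median chi-square per gene of 1.27 in A549 and 2.28 in TD against 0.455 for sampling alone, and of 1.40 and 1.91 with pseudogenes left out. No pair was therefore taken as copies of 1 library. These values decide that only if both files of a pair were aligned and counted alike, and they decide nothing further. This condition was not tested. The TD replicates stood apart in processed pseudogenes, the intronless copies of mRNAs. The median log2 ratio of TD replicate 2 over replicate 1 was -2.47 over 1656 processed pseudogenes and 0.10 over 13208 protein-coding genes. Processed pseudogenes held 0.831%, 0.853% and 0.803% of gene counts in A549 replicates 1 and 2 and TD replicate 1, and 0.151% in TD replicate 2. The biological coefficient of variation was 20.1% with all genes and 7.90% with pseudogenes left out, and 9423 genes were then called.

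**Figure D3:**
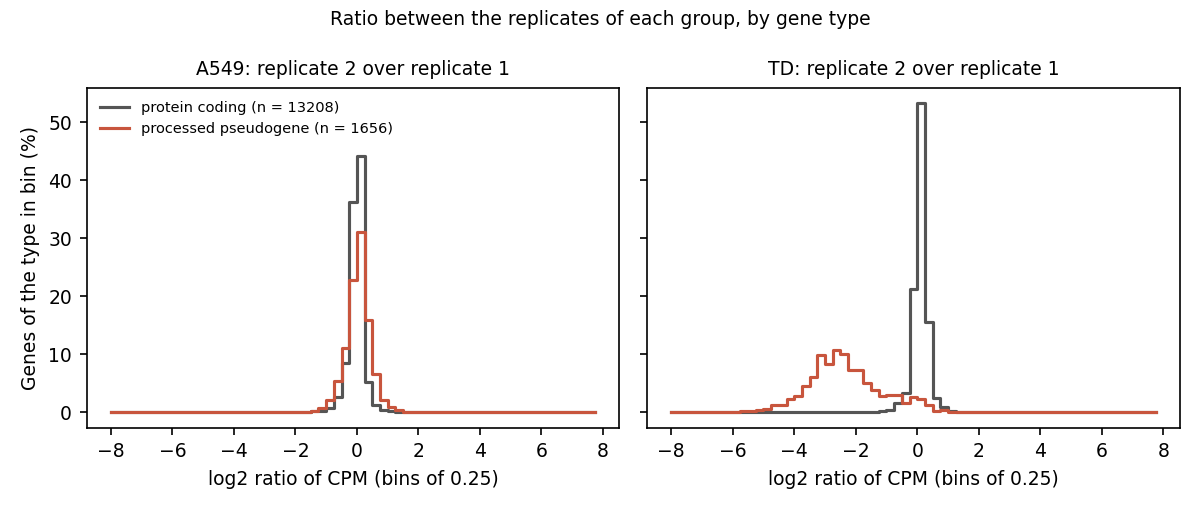
Distribution of the log2 ratio of replicate 2 over replicate 1 (bins of 0.25) in A549 and in TD, as the percent of genes of each type, for 13208 protein-coding genes and 1656 processed pseudogenes. Both types centre near 0 in A549, while processed pseudogenes centre at -2.47 in TD.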

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

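Reads outside annotated genes enter no comparison and stood out in TD replicate 1, where they made up 7.79% of all counted reads, above the 6.86% and 6.12% of the A549 replicates. The share in TD replicate 2 was 6.51%, between the A549 values, so the difference was not shared by the TD libraries. No explanation was tested for this value.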

How the results depend on the processing

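Leaving out pseudogenes was the only alternative chosen after the data were seen. Of 1718 values of 102 named genes under alternatives, 1685 kept direction and call, 33 lost the call and 0 changed direction, and 90 of the genes kept both under every alternative run. Among genes called both in the comparison and under an alternative, 0 changed sign, and the largest shift of the median change of all genes was -0.07 on the log2 scale, with scaling by library totals. Counts of called genes lay within 1.5 times of those reported, except as follows. With at least 5 CPM in 2 libraries, which tested 11175 genes, 950 genes were at least 2-fold higher and 1255 at least 2-fold lower. In the epithelial list 17 members were then lower and 1 higher, against 26 and 2 as reported. Members called lower were 3 among proteases and inhibitors and 4 among cytokines and chemokines, against 5 and 8. With each library left out in turn, 2114 to 5329 genes were higher, 2236 to 6140 lower and 1444 to 4096 at least 2-fold lower. The lowest counts came without an A549 library, when the spread is estimated from the TD pair alone (coefficient of variation 34.1% and 34.0%), and the highest without TD replicate 1. The spread comes from the A549 pair without either TD library (7.08%), so it does not account for the difference between these. Of the genes at least 2-fold lower, 1742 of 4096 were pseudogenes without TD replicate 1 and 219 of 2615 without TD replicate 2, which left 2354 and 2396 others. Of the 7642 calls, 7456 remained without TD replicate 2, 7547 without TD replicate 1, 4318 without A549 replicate 1 and 4442 without A549 replicate 2. With all libraries thinned to the smallest total, 7646 genes were called, so the greater depth of TD replicate 2 did not set the count.

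Replicate numbers are shared between the groups, but no label ties same-numbered libraries to a shared day, and the correlation of their deviations was -0.08. With the replicate number as a block, 5811 genes were called, 2964 higher and 2847 lower, and the YAP list had an adjusted p of 0.0581 by camera. The named genes PRSS8 (adjusted p = 0.0883 by edgeR), COL3A1 (0.0614), FBLN1 (0.0897) and CD14 (0.103) then lost their calls.

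Of the 13 lists called by camera, 12 were called under every alternative that kept the preset correlation and 0 with an estimated correlation, whose p was the highest over the alternatives of each. Those adjusted p-values were 0.078 for the epithelial, collagen and interferon-stimulated lists, 0.147 for the mesenchymal and lung lineage lists, 0.17 for integrins and laminins, 0.192 for proteases, 0.199 for TGF-β targets, 0.204 for NRF2 targets, 0.402 for the transcription factors, 0.417 for YAP targets, 0.534 for glycolysis and hypoxia and 0.557 for cholesterol synthesis. With few residual degrees of freedom such a correlation is poorly known, and camera then also takes its p from those few degrees of freedom. The estimate was below the preset 0.01 for the epithelial (-0.020), collagen (-0.019) and lung lineage (-0.0093) lists. Correlation therefore did not raise the p of these lists, and their lost calls are no evidence of correlated members. Fry, which does not compare a list with other genes, called all 13. The YAP list lost its call with limma-voom (0.0503) and the stricter filter (0.13), and ranged from 0.00101 to 0.066 with a library left out. Other lists gained a call. The pathway component list had 0.00835 without a filter, 0.0271 with fry and 0.0197 to 0.0997 with a library left out. Antigen presentation had 0.0453 with upper quartiles, 0.0178 with fry and 0.0133 to 0.093 with a library left out. The ferroptosis list had 0.0225 without a filter and 0.0205 with fry, and the drug transporter list had 0.0208 with fry.

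In lists that were not called, the sign of the direction changed at these adjusted p-values, and with a library left out only where that library is named beside the range. Proliferation had 0.968 with upper quartiles, 0.866 with library totals, 0.969 with limma-voom, 0.787 with the stricter filter, 0.949 with the replicate block, 0.983 without the 20 most abundant genes, 0.973 with fry and 0.398 to 0.927 with a library left out (sign changed without A549 replicate 1, A549 replicate 2 or TD replicate 2). Mitochondrial mRNAs had 0.968 with upper quartiles, 0.866 with library totals, 0.799 with the stricter filter, 0.925 without the 20 most abundant genes, 0.993 with protein-coding genes, 0.997 without pseudogenes, 0.973 with fry and 0.333 to 0.402 with a library left out (changed without A549 replicate 1 or TD replicate 2). Receptor tyrosine kinases had 0.966 with protein-coding genes, 0.933 without pseudogenes, 0.973 with fry and 0.721 to 0.986 with a library left out (changed without TD replicate 2, 0.843). Drug transporters had 0.969 with limma-voom, 0.949 with the replicate block and 0.721 to 0.973 with a library left out (changed without A549 replicate 1 or 2), and cytokines had 0.407 with the stricter filter. The cause of these changes was not tested. Camera was not run under the DESeq2 test, nor with robust dispersion, which changes no value that camera uses.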

Other observations

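The gene groups described first, and the tests on intronic genes, on CDKN2A, on neighbouring genes and on the scaling of the interferon-stimulated genes, were chosen after the values concerned had been seen.

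Several RNAs of liver-type plasma proteins and of gut-type brush borders were lower in TD than in parental A549 cells, with no test of these groups against other genes. Of 13 tested genes of the first group, all 13 fell by edgeR's test, while APOB, TF, TTR and HP had at most 6 counts in any library and were not tested. The fibrinogen chains FGA, FGB and FGG fell from 162 ± 14.9 to 0.0959 ± 0.0382 CPM, from 129 ± 11.1 to 1.76 ± 0.193 CPM and from 41.2 ± 4.10 to 0.0714 ± 0.00343 CPM. CP, the copper carrier ceruloplasmin, fell from 107 ± 6.67 to 0.455 ± 0.156 CPM, while HNF4A, a hepatic and intestinal transcription factor, fell only from 214 ± 0.0195 to 77.0 ± 6.14 CPM and the complement gene C3 from 169 ± 13.8 to 99.96 ± 10.6 CPM. Of 13 brush border and gut-type genes, 10 fell and 0 rose, among them MYO1A, from 32.4 ± 1.12 to 0.0836 ± 0.0208 CPM, and USH1C, from 263 ± 2.26 to 22.9 ± 1.24 CPM. The intestinal factor CDX2 had means of 0.472 and 0.303 CPM and was not called (adjusted p = 0.323), nor were the brush border cadherins CDHR2 (0.645) and CDHR5 (0.119).

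Imprinted RNAs moved in both directions, with 5 of 12 higher and 4 lower. MEG3, a maternally expressed long RNA, rose from 0.572 ± 0.0972 to 91.4 ± 20.1 CPM, and its neighbours MEG8 and MEG9 had 1 count each in A549 against 73 and 184 in TD. H19 fell from 54.7 ± 2.22 to 0.214 ± 0.0103 CPM, while IGF2, which lies beside it, had means of 0.502 and 0.814 CPM and was not called (adjusted p = 0.251). Of 9 tested members of the AP-1 family and other immediate-early genes, 3 were higher, 2 lower and 4 not called (FOSB, FOSL1, JUND and EGR1). JUN rose from 21.0 ± 2.37 to 136 ± 5.15 CPM, FOSL2 from 160.0 to 403 CPM and IER2 from 32.4 to 56.4 CPM, while FOS fell from 20.4 ± 0.311 to 0.307 ± 0.191 CPM and ATF3 from 6.69 to 1.59 CPM.

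Genes of chromosome 5 were higher in TD as a body, and those of chromosome 10 lower. Over 9130 protein-coding genes with a mean log2 CPM of at least 3, the median log2 change was 0.56 on chromosome 5 (95% bootstrap interval 0.53 to 0.62, 413 genes) and -0.35 on chromosome 10 (-0.43 to -0.26, 361 genes), against 0.06 over all genes. Both medians had a permutation p = 0.0001 against 10000 random sets of genes, the smallest these can give (adjusted p = 0.00046 over 23 chromosomes). Genes were drawn singly for these p-values and intervals, though neighbouring genes are not independent, and the spread between libraries does not enter them. They can therefore be too small or too narrow, and the same holds for the limits from random sets below. In TD replicates 1 and 2 taken singly, with no test, the medians were 0.52 and 0.62 on chromosome 5 and -0.37 and -0.30 on chromosome 10. Smaller medians over a whole chromosome were called on 17 (0.23), 9 (0.21), 2 (-0.16), 22 (-0.10) and 19 (-0.01). The last pair depended on the library: chromosome 22 had -0.21 in TD replicate 1 and -0.01 in replicate 2, and chromosome 19 had -0.11 and 0.09, against 0.00 and 0.11 over all genes. Base composition and gene length are argued against, since after a fit on both the medians were 0.50 on chromosome 5 and -0.41 on chromosome 10. A swap with a line that expresses CDKN2A, a gene A549 is known to have lost, is argued against by 0 CDKN2A counts in TD and 0 in A549. A copy-number difference that arose or was selected in the TD line is a candidate explanation. Windows of 40 neighbouring genes had medians above 0.34, the upper limit from random sets, in 89.47% of 38 windows on chromosome 5. Without genes changed over 4-fold, with the windows and the limit drawn anew, the share was 88.89%. Both shares are just under the 90% that the test required. With no DNA measured here, a copy-number difference cannot be told apart from regulation along the chromosome. The windows gave the pattern a shape. On chromosome 5 the medians were 0.55 to 0.84 over most of the gene order and 0.19 in the last window, from FAF2 to TRIM7. On chromosome 10 the first windows, from ZMYND11 to RUFY2, lay between 0.00 and 0.22, and the 23 windows from CSTF2T to ECHS1 all lay below the lower limit of -0.25. Elsewhere 26 of 759 windows, which overlap, lay above the upper limit and 28 below the lower, and some of these shifts were about as large as that of chromosome 10. Of the 28, 23 lay on chromosome 2 between ACP1 and TMEM185B, in the first part of its gene order, with medians down to -0.52. Of the 26, 13 lay on chromosome 9 between INVS and DPP7, with medians up to 0.52, 7 on chromosome 17 and 3 each on chromosomes 3 and 12.

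The fall of the interferon-stimulated genes went with interferon RNA in the parental cells. Scaling or filtering is argued against by the size of the fall. The median log2 change of the list was -5.10, while the largest shift of the median of all genes under an alternative was -0.07. The lowest number of members called lower was 30 of 30 over 17 alternatives, a count that such shifts could hardly move. Blood cells in the parental cultures are argued against by PTPRC, the abundant leukocyte RNA of CD45, with 2 counts in A549 and 7 in TD. Interferon made by the parental cells is a candidate explanation: IFNB1, IFNL1, IFNL2 and IFNL3 together had 723 counts in A549 and 14 in TD, with 329 and 394 in the A549 replicates and 3 and 11 in the TD replicates. IFNL2 and IFNL3 are near-identical, so only their sum is meaningful. IFNE, an interferon of epithelia, went the other way, with 62 counts in A549 and 430 in TD. Whether the parental level or the TD level is the unusual state, and whether TGF-β sets it, stays open, since no untreated later culture was analysed here.

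Processed pseudogenes were low in TD replicate 2, which no group difference explains, so no biological explanation was tested. Greater depth of that library is argued against, since the median log2 ratio to replicate 1 was -2.47 before and -2.43 after thinning to the total of replicate 1. Genomic DNA in the other libraries is argued against by sense intronic genes, whose median ratio was -0.0842 (95% interval -0.23 to 0.01, 100 genes). Reads of parent genes that were given to the copies in 3 libraries and less so in TD replicate 2 are a candidate explanation. Copies of more abundant parents dropped more, but this cannot decide the question. The ratio was not adjusted for the copies' own counts, and a prior count of 2 damps the drop of copies with few counts. If copies of abundant parents hold more counts, an equal loss over all copies could give the same sign. Across 1307 copies, which are not independent, Spearman's rho of the ratio with the parent's level was -0.223 (p = 0.0001, the smallest that 10000 permutations give), while the 496 parents had a median ratio of 0.16. Whether that library was aligned or counted with other settings was not tested.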
